A study of Sus scrofa with 12 samples.

How the data were processed

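Poly(A) RNA of longissimus dorsi muscle was sequenced in 6 samples of Laiwu and 6 of Yorkshire pigs on an Illumina NovaSeq, per the labels' protocols and the series' design text. The kit marks strand with dUTP, but whether counting used the strand is not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart. The design text says that the authors filtered reads with FastQC and aligned them with HISAT2 2.2.1 to the pig genome Sscrofa11.1, and the submitters' processing notes also name cutadapt 1.9, StringTie 1.3.4d, DESeq2 and edgeR without a role. The deposited table gives, per the file headers, a raw count and an FPKM value, a count scaled by gene length and library total, per gene and library. The counts deposited by the authors are whole numbers, and FPKM over count scales inversely with the library's total count, within 1% in each library. Annotation release and filters are not given in the sources used here. No gene of the mitochondrial genome was analysed here. The labels name breed and number only and do not say that libraries come from separate animals, so p-values measure the spread between these samples.

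Depth was 54961358 to 67285809 counts per library, and a count of 0 allows up to 3 counts, or 0.0446 to 0.0546 CPM. Such limits cover counting error only. Gene names were taken from the deposited table. Of 8541 IDs without a symbol, 130 were named from a table of gene names. Coordinates are those of the deposited table.

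Genes with a mean of at least 0.5 FPKM over the 12 libraries were tested (11205), and 12066 were left out. The tests, gene lists, named genes and first set of alternatives were chosen before the data were examined. The planned test was limma on log2(FPKM + 1), to be replaced by edgeR's quasi-likelihood test if counts were present. Counts were present, so edgeR 4.0.16 with TMM normalization and robust estimation was the main test, Laiwu minus Yorkshire, with no covariate, a Benjamini-Hochberg adjusted p under 0.05 and a standard error taken from the fold change and its F statistic. It was tested on simulated counts with 200 genes changed. limma 3.58.1, DESeq2 1.42.0 and R 4.3.3 were used for the alternatives, and Python 3.11.15 with matplotlib 3.10.9 for figures. DESeq2 gave no adjusted p for 10 genes.

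Of 32 fixed gene lists, the 27 with at least 5 tested members were tested with camera on log2(FPKM + 1) at a preset correlation of 0.01, two-sided, with adjustment over lists. Beside it stood camera with an estimated correlation, fry and an exact permutation test of list scores between the breeds. A score is the mean over members of log2(FPKM + 1) centred per gene. Relations within a breed were tested by exact permutation of pairings, two-sided, and adjusted over 8 relations. Terms of the deposited gene annotation were to be tested among called genes, which could not be done with 0 called genes.

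The genes named were fixed by a rule. It took up to 10 genes per direction with an adjusted p under 0.05, at least 5 FPKM and no overlap between breeds (0 qualified), for each list up to 4 members past the threshold or otherwise the 2 of highest mean FPKM, a fixed panel of genes of muscle and fat, and sex-linked genes as levels only. The values of 1 gene that the rule took are not reported here. Any other gene is said to have been chosen after its values were seen. Fold changes are given for the panel, for lists that camera called and for the genes of smallest p, and levels for the others. That limit was set after the data were seen, when 28 of the 76 tested named genes proved to change sign under at least 1 alternative, and it keeps most sign changes of the other genes out of the text.

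The alternatives fixed in advance were other pseudocounts (0.1 and 0.01), low-value filters, scalings, limma settings, library weights, an exact rank-sum test, DESeq2, a replicate block, a limit on the fold change, an adjusted p under 0.01 and leaving out each library. Pseudocounts, rescaling to TPM, quantile normalization and weights apply to the log scale and were run with limma. Added after the data were seen were edgeR's own low-count filter, library size without TMM, voom with quality weights, camera on log2 CPM, and other measures of the distance between libraries. The distance between a pair was the median absolute deviation, scaled to an SD, of the difference in log2 CPM. Gene length was taken as count over FPKM.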

Results

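The transcriptome of longissimus dorsi, the long muscle of the back, was measured in pigs of 2 breeds. The Laiwu is a Chinese breed known for muscle rich in fat, and the Yorkshire is a lean Western breed. Each breed contributed 6 libraries, 12 in all, from animals described as equal in weight. Between 54961358 and 67285809 counts were assigned to genes in each library, and 17214 to 17739 of the 23271 listed genes had at least 1 count. The 10 genes with most counts held 25.3% to 32.6% of a library's total. The comparison addresses which genes of this muscle differ in level between the breeds.

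No single gene differed between Laiwu and Yorkshire muscle by edgeR or limma once all tested genes were taken into account, and DESeq2 called 1, CILP. The largest fitted fold changes among the genes named in advance were those of the adipocyte genes ADIPOQ and PLIN1, and neither passed edgeR's test. ADIPOQ, which encodes the fat cell hormone adiponectin, had a mean of 37.1 ± 25.7 FPKM (SD, n = 6) in Laiwu and 11.5 ± 7.27 FPKM (SD, n = 6) in Yorkshire, and the Laiwu libraries ran from 9.54 to 77.2 FPKM. The smallest p by edgeR belonged to CILP, which encodes an extracellular protein of cartilage and other connective tissue. CILP was at 19.3 ± 3.85 FPKM (SD, n = 6) in Laiwu and 11.3 ± 1.26 FPKM (SD, n = 6) in Yorkshire, with no overlap between the breeds.

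edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 11205 genes at an adjusted p under 0.05, so 0 were higher and 0 lower in Laiwu, with or without a limit of 1 on the absolute log2 fold change. The smallest adjusted p was 0.912. The number of genes at an unadjusted p under 0.05 was 498, against 560.3 expected by chance, and it was 281 without Laiwu 3 and 293 without Yorkshire 5. limma on log2(FPKM + 1) also called 0 genes, with 391 at an unadjusted p under 0.05. DESeq2 called 1 gene, CILP, with an adjusted p of 0.0121, and had 569 at an unadjusted p under 0.05. CILP (ENSSSCG00000004928; Sscrofa11.1 chromosome 1, 163237322 to 163252406) had a log2 fold change of 0.74 ± 0.14 (SE) and an edgeR adjusted p of 0.912. Chosen after their values were seen, the 5 named genes next in order of p were HSPA12A, MAPK11, KLF16, HACD2 and EFEMP1. Their log2 fold changes were 0.54, -0.61, -0.67, 0.86 and 0.79, each with an edgeR adjusted p of 0.912, and by limma on log2(FPKM + 1) those of HSPA12A, MAPK11 and HACD2 were 0.18, -0.32 and 0.53. HSPA12A lay near the minimum of 0.5 FPKM for testing, at a mean of 0.598 FPKM in Laiwu and 0.406 FPKM in Yorkshire. MAPK11 was at 0.955 and 1.44 FPKM. The 6 libraries of one breed lay entirely above or below the 6 of the other for 20 genes, where chance gives 0.216%, or 24.3 genes. On simulated counts with the same means, library sizes and dispersions, the edgeR test recovered 78% of 200 genes changed 2-fold, 96% of those changed 4-fold and 16% of those changed 1.5-fold. It also called 12 unchanged genes at 2-fold, 6 at 4-fold and 0 at 1.5-fold. Simulated genes were drawn independently of each other, unlike real ones, so these rates do not rule out 2-fold differences here. Of the real genes, 60 had an absolute fitted log2 fold change of at least 1, and 0 of them passed. The SE was 0.54 for ADIPOQ and 0.50 for PLIN1, against a median of 0.163 over the tested genes.

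Adipocyte markers as a group were called higher in Laiwu by camera with a preset correlation (adjusted p = 5.16e-08), a call that was lost with an estimated correlation (adjusted p = 0.743). Of the 14 tested members, 11 had a fitted fold change above 0 and 3 below, and their median log2 fold change was 0.85, or 0.52 on another scale by limma with library weights. On log2(FPKM + 1) without weights the mean list score was 0.294 in Laiwu and -0.294 in Yorkshire. No member passed adjusted over all genes, and 4 passed adjusted over the list alone, namely PLIN1, CIDEC, PPARG and ADIPOQ, each at 0.0457, CIDEC being named after its value was seen. The adjustment over a list alone was run for each of the 27 lists, with no adjustment across them, and no other list had a member past it. Members correlated at a mean of 0.507 within breeds, so these genes are not separate evidence. An exact permutation test of the list score over libraries gave p = 0.039 before and 0.666 after adjustment over 27 lists. The list score ran from -0.49 in Laiwu 2 to 0.83 in Laiwu 3 within Laiwu, and from -0.75 in Yorkshire 4 to 0.22 in Yorkshire 6 within Yorkshire.

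PLIN1, which encodes the coat protein of fat cell lipid droplets (ENSSSCG00000001844; chromosome 7, 55236348 to 55250797), was at 12.5 ± 7.30 FPKM in Laiwu and 3.95 ± 2.50 FPKM in Yorkshire (SD, n = 6 each), a log2 fold change of 1.61 ± 0.50 (SE). ADIPOQ (ENSSSCG00000039103; chromosome 13, 124633685 to 124646646) had a log2 fold change of 1.64 ± 0.54. PPARG, the nuclear receptor that drives fat cell differentiation (chromosome 13, 68302322 to 68433944), was at 2.06 ± 1.22 and 0.851 ± 0.245 FPKM, a log2 fold change of 1.23 ± 0.35 that was 0.65 by limma on log2(FPKM + 1). FABP4, a fatty acid binding protein of fat cells (chromosome 4, 55096404 to 55101896), was at 25.8 ± 12.4 and 16.0 ± 4.41 FPKM, a log2 fold change of 0.66 ± 0.27, or 0.44 without Laiwu 3. The members of highest mean level, PLIN4 and CFD, had log2 fold changes of 0.30 ± 0.20 (0.46 without Yorkshire 2) and -0.10 ± 0.12 (0.00497 without Yorkshire 5). LEP, the gene of the hormone leptin, averaged 0.373 ± 0.248 FPKM in Laiwu and 0.106 ± 0.0543 FPKM in Yorkshire, below the minimum for testing. All of these tested genes had an edgeR adjusted p of 0.912 or 0.921.

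**Figure D1:**
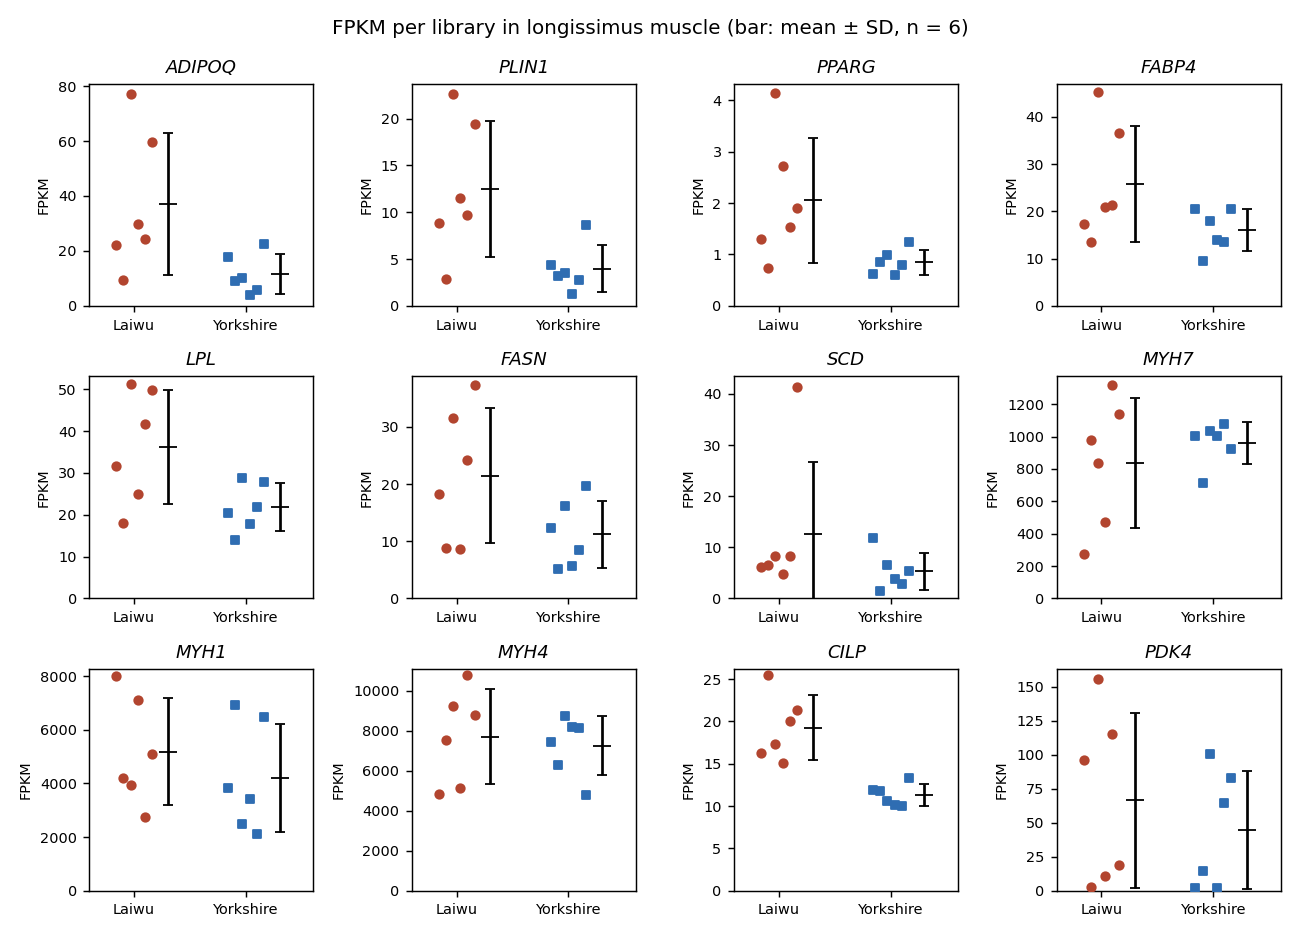
FPKM (y axis, linear, from 0) of 12 genes in each of the 6 Laiwu libraries (circles) and 6 Yorkshire libraries (squares), with the mean and SD as a bar beside each group, cut off at 0 for SCD. Levels of ADIPOQ in Laiwu span 9.54 to 77.2 FPKM and overlap the Yorkshire libraries, while those of CILP do not overlap.

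De novo lipogenesis and desaturation genes, which make and desaturate fatty acids, were called higher in Laiwu by camera with a preset correlation (adjusted p = 0.00569), with 9 of 14 members above 0, 5 below, 0 past the threshold and a median log2 fold change of 0.39. The adjusted p was 0.743 with an estimated correlation, and with the preset correlation it was 0.159 without Laiwu 6 (median 0.27), 0.0551 without Yorkshire 2 (median 0.38) and 0.152 by limma with library weights (median 0.16). That last median is on another scale than the others. On log2(FPKM + 1) without weights the mean list score was 0.142 in Laiwu and -0.142 in Yorkshire. FASN, the fatty acid synthase (chromosome 12, 920509 to 937561), was at 21.4 ± 11.8 FPKM in Laiwu and 11.2 ± 5.86 FPKM in Yorkshire (SD, n = 6 each), a log2 fold change of 0.90 ± 0.42 (SE). SCD, the stearoyl-CoA desaturase (chromosome 14, 111461569 to 111478020), had a log2 fold change of 1.23 ± 0.60, and 0.36 without Laiwu 6, the library in which it stood at 41.3 FPKM. ACSS2, an acetyl-CoA synthetase, had a log2 fold change of 0.02 ± 0.11, from -0.07 without Laiwu 6 to 0.07 without Laiwu 4. Genes of triglyceride synthesis and the lipid droplet coat (9 of 13 members above 0, camera adjusted p = 0.194) and of fatty acid uptake and lipolysis (7 of 13 above 0, adjusted p = 0.888) were not called, and 0 of their members passed. LPL, the lipoprotein lipase, was at 36.2 ± 13.6 and 21.8 ± 5.76 FPKM, a log2 fold change of 0.71 ± 0.24. FABP3, the fatty acid binding protein of muscle, had a log2 fold change of -0.22 ± 0.13, or -0.12 without Yorkshire 5. LPIN1 was at 19.3 ± 7.69 and 14.5 ± 3.01 FPKM, FITM1 at 55.6 ± 11.8 and 59.4 ± 8.22 FPKM, and VLDLR at 38.9 ± 5.53 and 38.8 ± 4.06 FPKM.

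Slow fibre genes, the contractile set of oxidative type I fibres, were called lower in Laiwu by camera with a preset correlation (adjusted p = 6.74e-06), with 13 of 14 members below 0, 1 above and 0 past the threshold. Their median log2 fold change was -0.53, and -0.32 without Yorkshire 5, and the adjusted p was 0.743 with an estimated correlation. The deviation of Yorkshire 5 correlated with gene length across genes at a Spearman's rho of -0.429. The slow fibre score was -1.39 in Laiwu 1 and -1.18 in Laiwu 4, without which the median was -0.37 and -0.43, and from 0.05 to 0.50 in the other 4 Laiwu libraries. In Yorkshire it ran from -0.74 in Yorkshire 2 to 0.92 in Yorkshire 5. MYH7, the slow myosin heavy chain (chromosome 7, 75648442 to 75673225), was at 836.8 ± 399.2 FPKM in Laiwu and 959.6 ± 130.5 FPKM in Yorkshire (SD, n = 6 each), a log2 fold change of -0.23 ± 0.29 (SE) that ran from -0.41 without Laiwu 5 to -0.05 without Laiwu 1. TNNC1, the slow troponin C, had a log2 fold change of -0.53 ± 0.31, or -0.33 without Yorkshire 5. Fast fibre genes were not called (4 of 14 above 0, 10 below, adjusted p = 0.194). The fast myosin heavy chains MYH1 (chromosome 12, 55225590 to 55249340) and MYH4 (chromosome 12, 55190433 to 55212813) had log2 fold changes of 0.27 ± 0.35 and 0.06 ± 0.19. With 1 library left out, that of MYH1 ran from 0.08 without Laiwu 1 to 0.49 without Yorkshire 2, and that of MYH4 from -0.05 without Laiwu 5 to 0.16 without Laiwu 1. TNNI2, the fast troponin I, was at 6163 ± 812.4 and 7075 ± 1510 FPKM. MYH1, MYH4 and MYH8 are closely similar neighbours, so the division of reads among them is uncertain, and MYH2 was not analysed here.

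Nuclear genes of oxidative phosphorylation were called lower in Laiwu by camera with a preset correlation (adjusted p = 9.66e-05), with 33 of 44 members below 0, 11 above, 0 past the threshold and a median log2 fold change of -0.15. The adjusted p was 0.743 with an estimated correlation, and 0.109 with the preset correlation without Yorkshire 5, where the median was -0.04. The median was -0.06 by limma on TPM, -0.07 on TPM without the 20 highest genes, -0.09 after quantile normalization and -0.06 with library weights. These limma values are on another scale than edgeR's -0.15. On log2(FPKM + 1) without such changes the mean list score was -0.0447 in Laiwu and 0.0447 in Yorkshire. How much of the drop is one of scale was not tested. The deviation of Yorkshire 5 correlated with gene length across genes at a Spearman's rho of -0.429. COX4I1, a subunit of cytochrome c oxidase, had a log2 fold change of -0.25 ± 0.13 (SE), or -0.12 without Yorkshire 5, and ATP5PO, a subunit of ATP synthase, one of 0.03 ± 0.11, from -0.03 without Laiwu 3 to 0.10 without Yorkshire 5. None of the other energy lists was called. Camera's adjusted p was 0.194 for mitochondrial fatty acid oxidation (15 of 21 members above 0), 0.64 for the tricarboxylic acid cycle (9 of 21), 0.0760 for regulators of mitochondrial biogenesis (10 of 12) and 0.391 for glycolysis and glycogen (8 of 20), with 0 members past the threshold in each. For the tricarboxylic acid cycle the median log2 fold change was -0.01 and the mean 0.02. GAPDH, the glycolytic dehydrogenase, was the most abundant of the named genes at 18387 ± 2753 and 19717 ± 2955 FPKM, and ALDOA, the muscle aldolase, was at 11801 ± 1051 and 12858 ± 1223 FPKM. ACADM was at 77.2 ± 14.5 and 65.2 ± 11.7 FPKM, MDH2 at 214.1 ± 31.6 and 209.96 ± 15.2 FPKM, SUCLG1 at 179.2 ± 14.2 and 186.2 ± 18.7 FPKM, PRKAA2 at 41.9 ± 6.81 and 38.05 ± 7.49 FPKM, and ESRRA at 20.1 ± 3.05 and 21.8 ± 1.71 FPKM. PPARGC1A, a coactivator of mitochondrial genes, had a log2 fold change of 0.19 ± 0.16, or 0.10 without Laiwu 6. PDK4, a kinase that holds back pyruvate oxidation, ranged from 2.51 to 155.7 FPKM within Laiwu and from 2.30 to 100.9 FPKM within Yorkshire.

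Extracellular matrix genes were called higher in Laiwu by camera with a preset correlation (adjusted p = 3.36e-06), with 23 of 24 members above 0, 1 below, 0 past the threshold and a median log2 fold change of 0.35, or 0.21 without Laiwu 4. The adjusted p was 0.743 with an estimated correlation. The member below 0, named after its value was seen, was TIMP1, an inhibitor of matrix proteases, at 2.72 ± 1.26 FPKM in Laiwu and 5.92 ± 5.67 FPKM in Yorkshire (SD, n = 6 each). COL3A1, a fibrillar collagen chain, had a log2 fold change of 0.39 ± 0.27 (SE), or 0.26 without Laiwu 4, and SPARC, a collagen binding protein, one of 0.18 ± 0.14, or 0.11 without Laiwu 4. Markers of fibro-adipogenic progenitors, the connective tissue cells of muscle that can turn into fat cells, were called higher in Laiwu as well (adjusted p = 0.0110), with 9 of 9 members above 0, 0 past the threshold and a median log2 fold change of 0.20. The adjusted p was 0.743 with an estimated correlation, and with the preset correlation it was 0.0696 without Laiwu 3 (median 0.13) and 0.0603 by limma with library weights (median 0.12). That last median is on another scale than the others. GSN and CLEC3B of this list had log2 fold changes of 0.20 ± 0.18, or 0.30 without Laiwu 2, and 0.12 ± 0.15, from 0.03 without Laiwu 3 to 0.21 without Laiwu 2.

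Markers of the other cell types in muscle were not called. Camera's adjusted p was 0.99 for endothelial markers (6 of 11 members above 0), 0.391 for smooth muscle and pericyte markers (4 of 11) and 0.139 for macrophage markers (2 of 9), with 0 members past the threshold. The endothelial list had a median log2 fold change of 0.01 and a mean of -0.01. PECAM1 was at 13.3 ± 3.60 FPKM in Laiwu and 13.1 ± 4.77 FPKM in Yorkshire, CDH5 at 9.03 ± 2.20 and 8.53 ± 2.49 FPKM, CNN1 at 24.8 ± 8.80 and 33.95 ± 8.88 FPKM, and DES at 1616 ± 181.0 and 1865 ± 287.1 FPKM. The macrophage list had a median log2 fold change of -0.30 and a mean of -0.44. Its only 2 members above 0 were the complement genes C1QA and C1QC, made by macrophages. They were at 4.18 ± 3.25 and 8.11 ± 4.64 FPKM in Laiwu and at 3.30 ± 1.40 and 7.23 ± 2.46 FPKM in Yorkshire (SD, n = 6 each). Both were highest in Laiwu 4, at 10.6 and 17.3 FPKM, where the next Laiwu values were 4.18 and 7.95 FPKM. Lymphocyte, nerve and Schwann cell, erythroid, cell cycle and mitochondrially encoded lists had fewer than 5 tested members and were not tested.

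Genes of muscle growth and of protein turnover, which bear on meat yield and tenderness, were not called. Camera's adjusted p was 0.667 for myogenic and satellite cell genes (7 of 16 members above 0), 0.147 for insulin-like growth factor, insulin and myostatin signalling (15 of 17), 0.172 for atrophy and autophagy (12 of 18), 0.827 for calpains and cathepsins (4 of 10) and 0.521 for calcium handling and excitation (5 of 13), with 0 members past the threshold. The myogenic list had a median log2 fold change of -0.03 and a mean of 0.02. MSTN, which encodes the growth inhibitor myostatin, had a log2 fold change of 0.24 ± 0.44 (SE), MYOD1 -0.12 ± 0.23, MYOG -0.24 ± 0.22 and PAX7 0.03 ± 0.22. The protease gene CAPN1 had a log2 fold change of -0.07 ± 0.10 and that of its inhibitor, CAST, 0.09 ± 0.14. The meat quality genes PHKG1, PRKAG3 and RYR1 had log2 fold changes of -0.18 ± 0.12, -0.07 ± 0.20 and 0.15 ± 0.17. With 1 library left out, the log2 fold change of RYR1 ran from 0.03 without Yorkshire 5 to 0.23 without Yorkshire 2, MSTN from 0.04 without Yorkshire 5 to 0.42 without Yorkshire 4, and MYOG from -0.38 without Laiwu 5 to -0.11 without Yorkshire 5. MYOD1 ran from -0.23 without Laiwu 5 to 0.03 without Laiwu 3, PAX7 from -0.12 without Laiwu 1 to 0.14 without Laiwu 6, and PRKAG3 from -0.19 without Yorkshire 2 to 0.04 without Laiwu 4. CAPN1 ran from -0.12 without Laiwu 2 to -0.02 without Laiwu 3, and CAST from 0.004 without Laiwu 3 to 0.18 without Laiwu 6. The lowest adjusted p among these 9 genes was 0.912 by edgeR. MYH8 was at 127.6 ± 48.3 FPKM in Laiwu and 97.9 ± 40.1 FPKM in Yorkshire, MYF6 at 85.9 ± 22.1 and 96.4 ± 51.8 FPKM, IRS1 at 36.5 ± 5.96 and 35.7 ± 13.0 FPKM, AKT2 at 27.04 ± 4.70 and 26.5 ± 4.13 FPKM, SQSTM1 at 186.6 ± 66.2 and 182.9 ± 59.9 FPKM, TRIM63 at 122.3 ± 66.6 and 125.5 ± 99.3 FPKM, CAPN3 at 264.04 ± 23.9 and 235.8 ± 39.99 FPKM, CTSD at 53.4 ± 7.05 and 59.4 ± 16.8 FPKM, and SLN at 2457 ± 340.4 and 2471 ± 425.5 FPKM. IGF1 averaged 0.333 and 0.345 FPKM, below the minimum for testing, and IGF2 was not analysed here.

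Cytosolic ribosomal protein genes were called lower in Laiwu by camera with a preset correlation (adjusted p = 1.90e-10), with 35 of 36 members below 0, 1 above, 0 past the threshold and a median log2 fold change of -0.21. Without Yorkshire 5, whose score of 0.52 was the highest of the 12 libraries, the median was -0.08, and the adjusted p was 0.743 with an estimated correlation. The median was -0.11 by limma on TPM, -0.12 on TPM without the 20 highest genes and -0.06 with library weights. These limma values are on another scale than edgeR's -0.21. On log2(FPKM + 1) without such changes the mean list score was -0.0797 in Laiwu and 0.0797 in Yorkshire. The deviation of Yorkshire 5 correlated with gene length across genes at a Spearman's rho of -0.429. RPLP1 and RPS2 had log2 fold changes of -0.29 ± 0.15 (SE) and -0.44 ± 0.24, the former -0.14 without Yorkshire 5. Stress, immune, clock and sterol lists were not called. The adjusted p was 0.99 for immediate early and heat shock genes (6 of 17 members above 0), 0.411 for interferon-stimulated genes (12 of 21), 0.0760 for antigen presentation (3 of 12), 0.378 for the circadian clock (11 of 17) and 0.0577 for cholesterol synthesis (3 of 15), with 0 members past the threshold. For interferon-stimulated genes the median and mean log2 fold changes were 0.01 and 0.03 while camera's direction was down. The small heat shock gene HSPB1 was at 569.7 ± 223.95 FPKM in Laiwu and 1200.3 ± 1171 FPKM in Yorkshire, and CRYAB at 443.8 ± 328.2 and 690.2 ± 681.8 FPKM (SD, n = 6 each). IFI6 was at 38.2 ± 58.3 and 36.3 ± 41.3 FPKM, B2M at 52.8 ± 22.7 and 50.7 ± 11.3 FPKM, CD74 at 41.6 ± 14.6 and 45.95 ± 8.98 FPKM, NR1D2 at 55.4 ± 8.52 and 43.9 ± 10.9 FPKM, BHLHE40 at 43.1 ± 13.5 and 45.7 ± 11.4 FPKM, IDI1 at 30.7 ± 4.67 and 32.9 ± 3.57 FPKM, and FDFT1 at 20.3 ± 3.13 and 19.1 ± 2.03 FPKM.

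**Figure D2:**
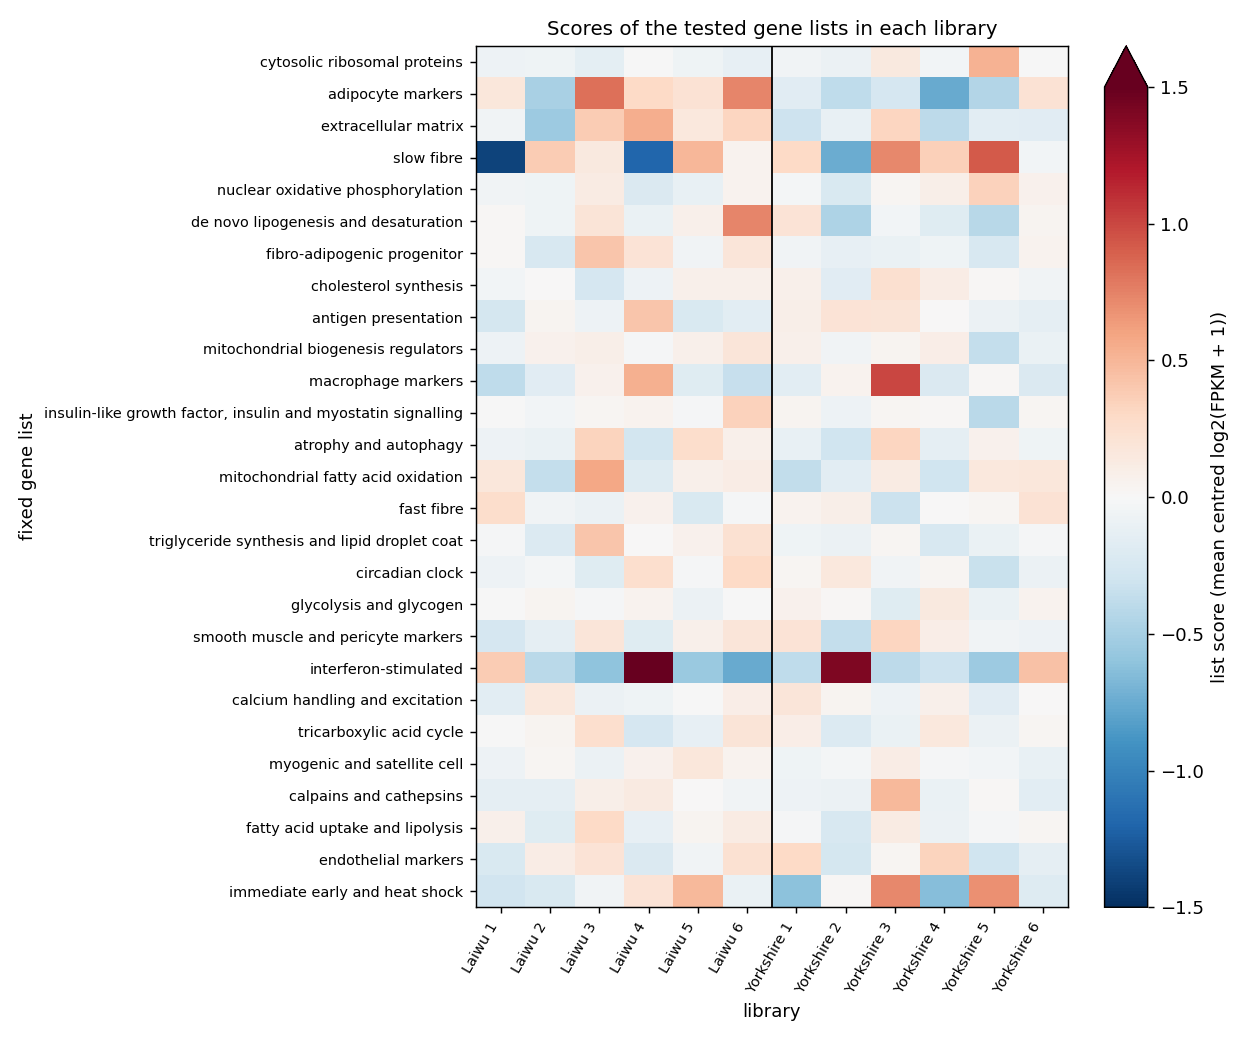
Score of each of the 27 tested gene lists (rows, in order of camera's p) in each of the 12 libraries (columns), where the score is the mean over members of log2(FPKM + 1) centred per gene and the colour scale ends at 1.5. The interferon-stimulated score is 1.71 in Laiwu 4 and 1.40 in Yorkshire 2, and the slow fibre score is lowest in Laiwu 1 at -1.39.

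Of the 27 lists tested, camera with the preset correlation called 7, of which 4 were higher and 3 lower in Laiwu, and the number was 11 without Laiwu 2 and 14 without Laiwu 4. None was called with an estimated correlation, by fry, whose lowest adjusted p was 0.661 for changes in either direction and 0.737 for 1 direction, or by exact permutation of list scores, where the lowest adjusted p was 0.666. The estimated correlation of the 7 called lists ran from 0.272 for fibro-adipogenic progenitors to 0.725 for slow fibre. The preset value was 0.01, so p-values with it treat members as nearly independent, which they were not.

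Within a breed, the adipocyte score was set against 4 other scores, giving 8 relations, and 0 passed after adjustment. Against the extracellular matrix score it had Pearson's r = 0.838 (exact permutation p = 0.0444, adjusted 0.356) and Spearman's rho = 0.829 (exact permutation p = 0.0583, adjusted 0.467) over the 6 Laiwu libraries, and r = 0.413 without the 2 libraries farthest from the median adipocyte score. In Yorkshire r was 0.240 (exact permutation p = 0.590, n = 6) and rho 0.143 (exact permutation p = 0.803), and r was 0.0247 without the 2 farthest libraries. Against de novo lipogenesis r was 0.654 in Laiwu and 0.542 in Yorkshire, with exact permutation p = 0.185 and 0.263, and 0.930 and 0.964 without the 2 farthest libraries. Spearman's rank correlation was 0.6 and 0.714, with exact permutation p = 0.242 and 0.136. Against slow fibre r was -0.035 and -0.194, with exact permutation p = 0.965 and 0.725, and turned to 0.390 and 0.0606 without the 2 farthest libraries. Spearman's rank correlation was -0.0857 and -0.429, with exact permutation p = 0.919 and 0.419. Against endothelial markers r was 0.325 and -0.273, with exact permutation p = 0.560 and 0.613, and 0.906 and 0.982 without the 2 farthest libraries, a turn of sign in Yorkshire. Spearman's rank correlation was 0.543 and -0.0286, with exact permutation p = 0.297 and 1. The adjusted p was 0.7 or more for r and 0.544 or more for rho in these 7 relations. Each r without the 2 farthest libraries rests on fewer than 6 libraries and was not tested, so a high value there shows no relation.

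No difference was found between distances within and between breeds. The spread of a pair, the robust SD of the log2 ratio over the tested genes, averaged 0.417 over the 36 pairs of 1 Laiwu and 1 Yorkshire library and 0.418 over the 30 pairs within a breed (exact permutation of breed labels, one-sided p = 0.472). For 9 of 12 libraries the nearest library carried the label of the other breed (exact permutation p = 0.208). The smallest spreads between breeds, chosen after they were seen, were 0.205 for Laiwu 2 with Yorkshire 4, 0.215 for Laiwu 1 with Yorkshire 6, 0.245 for Laiwu 2 with Yorkshire 1, 0.247 for Laiwu 4 with Yorkshire 2 and 0.283 for Laiwu 5 with Yorkshire 3, and the next was 0.330. In 4 of these 5 pairs both libraries lay nearer to each other than to any of their own breed, but Yorkshire 1 lay nearest to Yorkshire 4, at 0.212, the second smallest spread of all 66 pairs, so that Laiwu 2, Yorkshire 1 and Yorkshire 4 were close to one another. Within these 5 pairs the variance was 9.77 to 17.5 times that of counting noise, so no pair agreed within sampling noise, which does not show that the libraries came from separate samples. Yorkshire 5 had the largest median spread to the others, at 0.654 against 0.355 to 0.463 for the other 11. The Y-linked genes EIF1AY and ZFY had counts in every library, EIF1AY from 21.3 to 27.3 FPKM and ZFY from 3.33 to 5.61 FPKM, and KDM5D ranged from 0.296 to 0.848 FPKM. XIST, DDX3Y, UTY, EIF2S3Y and USP9Y were not analysed here.

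**Figure D3:**
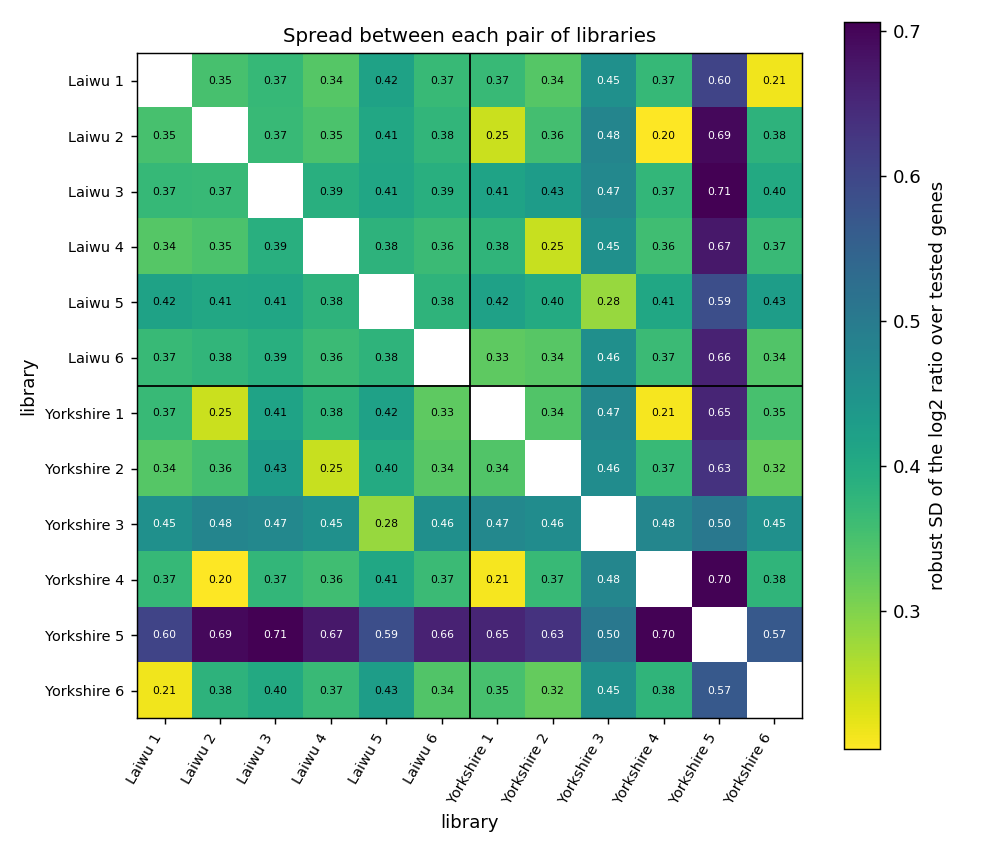
Robust SD of the log2 ratio over the tested genes (colour and printed value) for each pair of the 12 libraries, with lines between the breeds. The pairs of Laiwu 2 with Yorkshire 4 (0.205) and Laiwu 1 with Yorkshire 6 (0.215) are among the closest, and Yorkshire 5 is farthest from the rest.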

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

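The tests of a shared animal, of a shared state, of fat cell share, of distance against breed labels and of lost long transcripts were chosen only after the result was seen, as was the count of splits for the 0 called genes.

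A library was set apart when its gap to the next, over the range of the 6 libraries of its breed, exceeded Dixon's 95% critical value. This held for 25 of 222 groups of values. Chance gives about 1 in 20, or 11.1, only if values are normally distributed and groups independent. FPKM values were not put on a log scale, and some scores share genes with the named genes, so whether 25 exceeds chance cannot be told.

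Laiwu 4 was highest of its breed for the interferon-stimulated gene IFI6 (155.7 FPKM, next 29.5), B2M (97.1, next 53.1), C1QA (10.6, next 4.18), C1QC (17.3, next 7.95), BHLHE40 (70.2, next 40.4), IGF1 (0.693, next 0.348) and KDM5D (0.848, next 0.496). Yorkshire 2 was highest of its breed for IFI6 (118.9 FPKM) and B2M (72.8 FPKM) and lowest for MDH2 (180.1 FPKM). Laiwu 6 was highest for SCD (41.3 FPKM, next 8.28), ACSS2 (23.4 FPKM), the de novo lipogenesis score (0.73, next 0.20) and the score of insulin-like growth factor, insulin and myostatin signalling (0.35, next 0.06), and had the lowest total count of its breed, 55351545. Yorkshire 3 was highest for CAST (39.4 FPKM), the calpain and cathepsin score (0.49) and the macrophage score (0.999, next 0.05). Yorkshire 5 was highest for TNNI2 (10022 FPKM), RPLP1 (2030 FPKM) and the median spread to the other libraries (0.654), and lowest for the score of insulin-like growth factor, insulin and myostatin signalling (-0.41). The remaining values were CRYAB in Laiwu 5 (1100 FPKM, next 402.7), DES in Laiwu 1 (1955 FPKM) and GSN in Laiwu 2 (60.5 FPKM, lowest).

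Yorkshire 5 had the largest median spread to the other libraries, 0.654 against 0.355 to 0.463 for the other 11. Spearman's rho between its deviation from the mean library and gene length, across 11205 genes, was -0.429, against -0.114 to 0.181 in the other 11 libraries, so a loss of long transcripts is a candidate explanation for part of its distance. Removing each library's trend on length and mean level left its median spread at 0.553, above the 0.354 to 0.456 of the others, so these trends do not account for all of it. Its spread to Yorkshire 3 was then 0.397, below the 0.440 to 0.471 of Yorkshire 3 to the other Yorkshire libraries. Genes are not independent replicates, and no biological explanation was tested.

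In 4 of the 5 Laiwu and Yorkshire pairs of smallest spread both libraries lay closer to each other than to any library of their own breed (in the fifth, Yorkshire 1 was nearer to Yorkshire 4, at 0.212), and the mean spread between breeds minus that within breeds was -0.00196 (exact permutation p = 0.472 for a larger and 0.530 for a smaller value), so whether distances follow breed stays open. The bound written against it, a mean between breeds at or below that within breeds, was met. After this was seen, the verdict was changed from excluded to open, because the difference lay within the permutation spread. After removal of length and level trends, 5 of these 5 close pairs kept a smaller spread than each of the other 31 pairs of different breed, which argues against a shared length bias as the whole cause. Genes switched between 2 levels in the other 10 libraries numbered 44 to 71 per pair. They were on the same side in 74.5%, 79.5%, 81.25%, 81.25% and 83.1% of cases in the 5 close pairs. In the other pairs of different breed the median was 59.3% and the maximum 77.3%. The distant pair of Yorkshire 3 with Yorkshire 5 (spread 0.505) reached 83.7%, so whether paired libraries may share an animal or sample stays open. The close pairs also had the smaller spread in 27 of 27 lists, which met the bound of 20 lists written against a shared stress, interferon or feeding state; after this was seen, the verdict was changed from excluded to open, because the pairs had been picked for small spread over the same genes. A wrong label was not tested and stays open too.

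Adipocyte markers were called higher in Laiwu by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.743). Within breeds the members had a mean correlation of 0.507, the value that camera had already estimated, so this was no independent test. It lay above the 95th percentile of 0.175 over 1000 random lists matched on mean level. But 8 of the other 26 tested lists reached 0.507 too, interferon-stimulated (0.857) and ribosomal protein genes (0.674) among them. Whether a fat cell share that differs between libraries lies behind the correlation therefore stays open. The verdict on fat cell share was changed from fitting to open after these values were seen. None of the 14 tested members is in another list. The 3 most abundant in Laiwu, PLIN4, ADIPOQ and CFD, were at 72.5, 37.1 and 28.9 FPKM there and at 57.3, 11.5 and 30.3 FPKM in Yorkshire. In other splits of the 12 libraries, 80 of 100 (the real one included) gave at least as many called lists. The real split gave 7, and the others a median of 8 and 16 at most, so chance is not excluded for the number of called lists. The adipocyte list itself was called in 47 of the 100 splits. Its adjusted p by camera was 5.16e-08 in the real split. Splits with smaller values, 5.84e-15, 1.99e-13, 1.78e-11 and 2.03e-11, put 4 or 5 Laiwu libraries on the same side. A difference between the breeds in fat content stays open and was not tested beyond the list tests of adipocyte markers.

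For single genes the real split called 0 and the others 81 at most, and since all 100 of 100 splits must reach 0, this count decides nothing. Its verdict was changed from fitting to open after the count was seen. At an unadjusted p under 0.05, 48 of 100 splits gave at least the 498 genes of the real split, with 1976 at most in the others, so chance is not excluded. The split with 1976 such genes put Laiwu 1, 5 and 6 with Yorkshire 3, 5 and 6, and may reflect a structure of the samples other than breed, which was not tested.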

How the results depend on the processing

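Of these alternatives, those with edgeR's own filter, library size only, voom weights, camera on log2 CPM and other distances were chosen after seeing the data. Genes called numbered 0 under each of 33 alternatives except DESeq2, which called 1, CILP. The number of genes at an unadjusted p under 0.05 was 281 without Laiwu 3, 293 without Yorkshire 5, 1715 of 23271 genes with no low filter and 31 with an absolute log2 fold change of at least 1, where fewer genes can count. By limma 55.5% of such genes were higher in Laiwu on log2(FPKM + 1), 77.4% after rescaling to TPM and 72.8% on TPM without the 20 highest genes, and by edgeR 48.2%; the median log2 fold change of all genes was 0.02 by limma on log2(FPKM + 1) and 0.07 and 0.06 on TPM. Fixed lists called numbered 0 with an estimated correlation, 0 with fry and 0 with exact permutation of list scores, and 6 to 14 when 1 library was left out, with 11 without Laiwu 2 and 14 without Laiwu 4; the cause was not tested. The other alternatives called 6 to 8. Lipogenesis and progenitor calls were also lost with library weights (adjusted p = 0.152 and 0.0603), and the latter with edgeR's filter (0.0521). List scores differed for 0 lists and within-breed relations passed 0 times under every alternative run. The nearest library carried the other breed's label for 8 to 10 of the 12 under 8 added measures.

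Of 76 tested named genes, 28 changed sign under at least 1 setting, and 0 passed the threshold under any edgeR, limma or rank-sum setting. Of the 28, 3 had an absolute log2 fold change of at least 0.25 and were chosen after their values were seen. The HSPB1 log2 fold change was -1.10, -0.61 by limma without weights and 0.04 by limma with library weights. The CRYAB log2 fold change was -0.65, -0.29 by limma without weights, and 0.32 and 0.22 by limma and voom with weights. The C1QA log2 fold change was 0.34, and -0.21 without Laiwu 4. Among genes given with a fold change, the PAX7 log2 fold change was -0.00688 with the replicate block, -0.00900 with the block and median-ratio scaling, -0.0166 after quantile normalization, -0.0381 with library weights and -0.0875 with voom weights. The MSTN log2 fold change was -0.0386 and -0.00347, and the ACSS2 log2 fold change -0.0415 and -0.0365, with these 2 weightings. With 1 library left out, the PAX7 log2 fold change ran from -0.121 to 0.137, the MYOD1 log2 fold change from -0.23 to 0.0277, the ATP5PO log2 fold change from -0.0276 to 0.10, the PRKAG3 log2 fold change from -0.187 to 0.0443, the MYH4 log2 fold change from -0.0546 to 0.159, the ACSS2 log2 fold change from -0.0723 to 0.0657 and the CFD log2 fold change from -0.142 to 0.00497. The cause was not tested.

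No pairing of libraries by replicate number was seen, which does not show that none exists. Deviations of same-numbered libraries correlated from -0.272 to 0.331, and 1 of 6 Laiwu libraries matched best with its own number. With the replicate block edgeR called 0 genes, genes at an unadjusted p under 0.05 numbered 433, and camera 7 lists (8 with median-ratio scaling). Genes below a mean of 0.5 FPKM, LEP and IGF1 among them, were left out of the main test and were tested with no low filter.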

Other observations

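Some scores and genes differed widely among libraries within each breed. The interferon-stimulated score was 1.71 in Laiwu 4 and 1.40 in Yorkshire 2, 0.39 in Laiwu 1 and 0.44 in Yorkshire 6, and below 0 in the other 8 libraries. PDK4 was at 2.51 FPKM in Laiwu 2, 2.30 in Yorkshire 1 and 2.33 in Yorkshire 4, and at 155.7 FPKM in Laiwu 3, 115.0 in Laiwu 5 and 100.9 in Yorkshire 3. The small heat shock genes HSPB1 and CRYAB were at 3247 and 1720 FPKM in Yorkshire 5, 1961 and 1398 FPKM in Yorkshire 3, and 970.7 and 1100 FPKM in Laiwu 5, against 294.1 to 762.6 FPKM and 212.8 to 402.7 FPKM in the other 9 libraries. The slow fibre score was -1.39 in Laiwu 1, -1.18 in Laiwu 4 and -0.74 in Yorkshire 2, and -0.05 or more elsewhere. Some extremes were shared across breeds by libraries of small spread. The close pair Laiwu 4 and Yorkshire 2 had the highest interferon-stimulated scores. Low PDK4 marked Laiwu 2, Yorkshire 1 and Yorkshire 4, which lay close to one another. High HSPB1 and CRYAB were shared by the close pair Laiwu 5 and Yorkshire 3, but Yorkshire 5, in no close pair, was higher. In the close pair Laiwu 1 and Yorkshire 6 the slow fibre scores differed, at -1.39 and -0.05. The cause was not tested.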
